A study of Mus musculus with 6 samples.

How the data were processed

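RNA was sequenced from mouse embryos at the 4-cell stage that had been injected with a morpholino against Rbpms2 (knockdown, 3 samples) or with a non-silencing morpholino (control, 3 samples). A morpholino is a synthetic antisense oligomer that blocks translation or splicing of its target, and the labels do not say which kind was used. Per the labels' protocols, RNA was extracted with phenol and chloroform and libraries were built by tagmentation. The number of embryos in a library is not given in the labels.

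The authors deposited a table for each sample that gives, per the file headers, a read count and a TPM value for every listed gene. The deposited read counts are estimated counts that need not be whole, summing to a different total in each sample, and 21.9% to 23.3% of them differed from a whole number by more than 1e-06. The deposited TPM values are scaled for gene length by the authors and sum to the same total in each sample. The submitters' processing notes name HISAT2 2.0.4, Bowtie2 2.2.5 and RSEM 1.2.12, without roles or order, and the builds GRCm39 and mm39. The annotation used for counting, read trimming and the handling of strand are not given in the sources used here. The reference supplied for this work is of an earlier mouse build, so no coordinates are printed, and genes carry the symbols and NCBI gene IDs of the deposited tables. The tables listed 18974 genes in at least 1 sample, all typed as mRNA, and 13637 in all 6 samples. They listed 0 mitochondrially encoded genes, so transcripts of the mitochondrial genome were not analysed here. A gene not listed for a sample was taken as 0.

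Estimated counts were rounded to whole numbers. Genes were kept with edgeR's filterByExpr, which left 13283, and library sizes were scaled with TMM factors. The factors were 0.821, 0.814 and 0.923 in the controls and 1.195, 1.104 and 1.227 in the knockdown libraries. Knockdown was compared with control by edgeR's quasi-likelihood test (glmQLFit and glmQLFTest, edgeR 4.0.16 in R 4.3.3) over all 6 samples without covariates, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. A further count took only changes of at least 2-fold. CPM values printed for a gene or a list are scaled with the TMM factors unless stated otherwise. Fold changes are relative to the TMM scaling, under which the median log2 fold change of the tested genes was 0.03.

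A set of 29 gene lists with 945 entries (905 different genes) was fixed before the data were examined. Of the entries, 881 were found by symbol, 2 by NCBI gene ID, and 62 were not matched. Lists with at least 3 tested members were tested with limma's camera (limma 3.58.1, two-sided, preset inter-gene correlation of 0.01) with Benjamini-Hochberg adjustment over the 27 lists tested. Camera with an estimated correlation and limma's rotation test fry were run as well. Camera compares a list with the other genes, whereas fry asks whether the list's own members move. Marker lists of cumulus and granulosa cells, sperm, fibroblasts and stroma, and blood stood for cells that could be carried over with embryos.

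The rule for named genes was also fixed before the data were examined. It took Rbpms2 and its paralog Rbpms, and the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap and whose mean reached 5 TPM, leaving out symbols that are only clone or model numbers. It further took up to 4 members of each list with the smallest p, and the lineage factors Pou5f1, Nanog, Sox2, Cdx2, Tead4 and Gata6. A gene named outside this rule is said to have been chosen after its values were seen.

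Total estimated reads ranged from 18584800 to 23503511 in the controls and from 18696957 to 21040652 in the knockdown. The common biological coefficient of variation was 0.408. The test was run on simulated data with known answers over 13052 genes with the fitted dispersion, where it recovered 1.5% of genes changed 2-fold, 47.8% of those changed 4-fold and 86.4% of those changed 8-fold, with 5 false calls among 95. With a lower simulated dispersion, over 13147 genes, it recovered 70.1%, 94% and 100%. Far fewer genes were changed in these simulations than were called in the data, which makes the adjusted threshold stricter. The recovered shares therefore need not hold for the data. A simulated list of 40 genes raised 2-fold was recovered by camera, with 0 of the unchanged lists called. Genes were simulated independently of each other, so this could not show false calls that arise from correlation between genes. In the data the estimated correlation reached 0.948, in the cytosolic ribosomal list. For genes with 0 reads in the controls, a lower bound on the fold was taken from a floor of 3 reads in a library, and for genes with 1 to 3 reads a ratio with a 95% counting interval was computed. Intervals and floors cover counting error only, because reads amplified by PCR without molecular identifiers are not independent molecules.

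Genes with a count that was not whole in any library were taken to share reads with other genes. Transcript length relative to other genes was inferred from the ratio of estimated count to TPM, and transcript GC content was taken from the reference transcripts by gene symbol, with a value for 97.1% of tested genes. Alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom, voom with sample quality weights, median-ratio and upper-quartile factors, no filter, a stricter filter (50 reads in 3 libraries), a filter on the mean (1 CPM), genes listed in all 6 samples, the replicate number as a block, and each sample left out in turn. Scaling by library sizes alone, limma-trend on log2(TPM + 1), and a test of genes with whole counts only were added after the data were seen.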

Results

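The series profiled the transcriptome of mouse 4-cell embryos after injection of a morpholino against Rbpms2, an RNA-binding protein, and its title places the gene among maternal proteins that act in blastocyst formation. Control embryos received a non-silencing morpholino. Each group held 3 samples. Total estimated reads were 20405774, 18584800 and 23503511 in control replicates 1 to 3 and 21040652, 20549280 and 18696957 in knockdown replicates 1 to 3. The knockdown libraries listed more genes, 17046 ± 50 against 15585 ± 273 (mean ± SD, n = 3 each, exact permutation test, two-sided p = 0.1, the smallest this design allows). Nothing in the labels says that the replicates came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

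Rbpms2 (NCBI gene 71973) was measured in every sample. Its TMM-scaled level was 74.91, 72.93 and 70.48 CPM in the controls and 36.94, 30.05 and 48.46 CPM in the knockdown. Its log2 fold change was −0.92 ± 0.24 (SE), with a 95% interval of −1.58 to −0.26 and an adjusted p of 0.0326 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The fall depended on the scaling. With library sizes alone the log2 fold change was −0.44 (edgeR adjusted p = 0.221), and on the authors' TPM values it was −0.14 (limma-trend adjusted p = 0.758). The call, more than the size of the fall, depended on single libraries. It was lost with any library other than knockdown replicate 3 left out (log2 fold change −0.95 to −0.80, edgeR adjusted p = 0.0677 to 0.118). With the replicate number as a block the call was lost too. In TPM the controls stood at 41.54 ± 0.613 and the knockdown at 40.75 ± 20.6 (mean ± SD, n = 3), with knockdown replicate 3 at 64 and the other knockdown samples at 33.38 and 24.86. A morpholino need not lower the mRNA of its target, so the transcript level is an incomplete check of the labels. The paralog Rbpms (NCBI gene 19663) had a log2 fold change of −0.27 ± 0.36 (edgeR adjusted p = 0.568), which was 0.18 with library sizes alone, 0.36 on TPM and 0.04 without knockdown replicate 3.

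The knockdown and control libraries separated along the leading principal component, which held 75.7% of the variance. Of 13283 tested genes, 2292 rose and 1146 fell in the knockdown at an adjusted p under 0.05 in edgeR's quasi-likelihood test, and 2117 and 946 of these changed at least 2-fold. The rises started from low levels, with a median control mean of 2.34 CPM against 12.6 CPM in the knockdown. The falls came from more abundant transcripts, with medians of 65.2 CPM in the controls and 26.9 CPM in the knockdown. The groups did not overlap in 7837 tested genes (59%, against 10% by chance for 3 samples against 3). Rises made up 66.7% of the calls with TMM factors, 92.7% with library sizes alone and 95.3% on TPM. They made up 58.9% with limma-voom, 52.8% with sample quality weights and 51.1% (2910 rises and 2781 falls) without knockdown replicate 3. The median log2 fold change of all genes was 0.03 with TMM factors, 0.50 with library sizes alone and 0.55 on TPM. Knockdown replicate 3 lay apart from the other knockdown samples, with correlations of log2 CPM across genes of 0.877 and 0.874 to replicates 1 and 2, which correlated at 0.98 with each other.

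**Figure D1:**
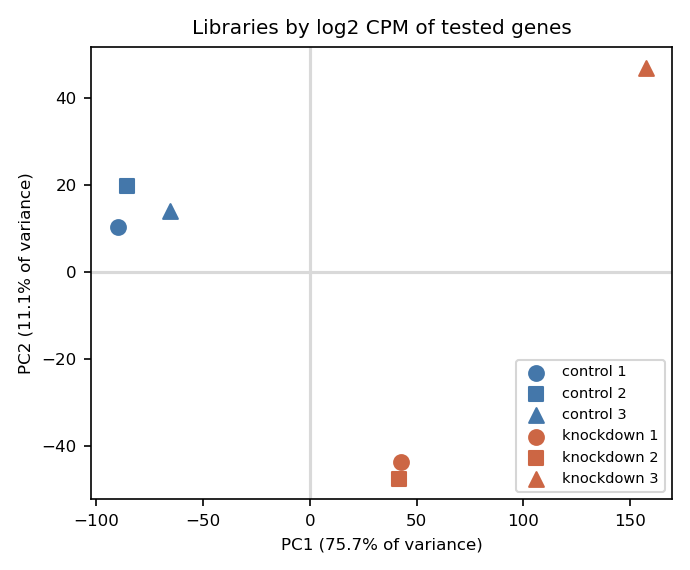
Principal components of log2 CPM over the tested genes, 1 point per library, with PC1 (75.7% of the variance) on the x axis and PC2 (11.1%) on the y axis. The 3 controls lie between −90.1 and −65.7 on PC1, knockdown replicates 1 and 2 at 42.6 and 41.6, and knockdown replicate 3 at 157.3.

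Transcripts of the 2-cell burst, which are switched on when the mouse embryo first activates its genome and normally decline by the 4-cell stage, were higher in the knockdown. Of 34 measured members 28 rose and 1 fell (29 and 1 adjusted over the list alone). The median log2 fold change was 3.63, and 3.0 without knockdown replicate 3. Tcstv1 rose from 6.07 to 246 CPM (log2 fold change 5.34 ± 0.40 SE, edgeR adjusted p = 0.00365). Zfp352 rose from 7.89 to 198 CPM (4.65 ± 0.38, edgeR adjusted p = 0.00365). Usp17la rose from 1.12 to 24.7 CPM (4.43 ± 0.46, edgeR adjusted p = 0.00574). Tmem92 rose from 4.98 to 49.5 CPM (3.31 ± 0.38, edgeR adjusted p = 0.007). The member that fell, named after its values were seen, was the homeobox gene Obox6 (−1.41 ± 0.38, edgeR adjusted p = 0.035). The list passed camera (adjusted p = 2.84e-17; adjusted p = 0.656 with an estimated correlation). In 26 of its members, Tcstv1, Usp17la and Tmem92 among them, reads were shared with other genes in at least 1 library. Their single values are uncertain, whereas the counts of Zfp352 were whole in every library.

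Maternal oocyte transcripts were also higher as a list. Of 46 measured members 13 rose and 0 fell (28 and 1 adjusted over the list alone). The median log2 fold change was 1.98, and 1.13 without knockdown replicate 3. Kit, the stem cell factor receptor of growing oocytes, rose from 1.19 to 12.9 CPM (log2 fold change 3.43 ± 0.62 SE, edgeR adjusted p = 0.0155; 2.53 without knockdown replicate 3). The oocyte growth factor Gdf9 rose from 5.0 to 52.3 CPM (3.38 ± 0.71, edgeR adjusted p = 0.0204; 2.21 without that library). Nlrp14 rose by 2.27 ± 0.48 (edgeR adjusted p = 0.0208; 1.64 without that library). Fbxw15 rose by 3.52 ± 0.72 (edgeR adjusted p = 0.0199; 2.58 without it and 4.17 without control replicate 3). The list passed camera (adjusted p = 8.96e-06; adjusted p = 0.705 with an estimated correlation). Its summed level went the other way, at 15900, 14870 and 11380 CPM in the controls and 8442, 10180 and 7558 CPM in the knockdown. In every library but knockdown replicate 3, most of that sum was Dppa3, a gene chosen after its values were seen. Dppa3 stood at 12360 CPM in the controls and 5770 CPM in the knockdown (edgeR adjusted p = 0.121). In knockdown replicate 3 it was 2598 of the 7558 CPM.

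Transcripts of the translation machinery, of mitochondrial respiration and of the proteasome were lower in the knockdown. Of 78 cytosolic ribosomal protein genes 0 rose and 23 fell (67 fell adjusted over the list alone). The median log2 fold change was −1.39, and all 78 were below 0. Without knockdown replicate 3 the ribosomal falls numbered 74, those of oxidative phosphorylation 42 (with 1 rise) and those of the proteasome 25 (with 1 rise). The medians of these 3 lists were then −1.01, −0.92 and −0.74, smaller in size than over all samples although more members were called. Rps4x fell from 1869 ± 223 to 548 ± 280 CPM (mean ± SD, n = 3; log2 fold change −1.77 ± 0.46 SE, edgeR adjusted p = 0.0325). Rpl35 fell from 2367 to 875 CPM (−1.44 ± 0.37, edgeR adjusted p = 0.0328). Rpl37 and Rpl39 each had a log2 fold change of −1.45 (edgeR adjusted p = 0.0271 and 0.032) and shared reads with other genes. The summed level of the list was 143600, 149400 and 165500 CPM in the controls against 75480, 85710 and 27720 CPM in the knockdown, lowest in replicate 3. Of 51 nuclear genes of oxidative phosphorylation 13 fell and 0 rose (36 and 1 adjusted over the list alone; median −1.26). Among them were the complex I subunits Ndufc2 (−2.02 ± 0.46, edgeR adjusted p = 0.0249), Ndufb2 (−1.26 ± 0.25, edgeR adjusted p = 0.0181) and Ndufv2 (−1.20 ± 0.30, edgeR adjusted p = 0.0311). Of 33 proteasome genes 6 fell and 0 rose (0 and 0 adjusted over the list alone; median −1.04). These included Psma3 (−1.52 ± 0.39, edgeR adjusted p = 0.0323), Psmd4 (−1.23 ± 0.33, edgeR adjusted p = 0.0352), Psma1 (−1.84 ± 0.49, edgeR adjusted p = 0.0356) and Psmd8 (−1.75 ± 0.50, edgeR adjusted p = 0.0418). Camera gave an adjusted p of 2.84e-17 for the ribosomal list, 2.42e-10 for oxidative phosphorylation and 4.79e-06 for the proteasome. For each of these 3 lists the call was lost at an adjusted p = 0.677 with an estimated correlation. The medians of the 3 lists were −0.96, −0.82 and −0.60 with library sizes alone and −0.73, −0.62 and −0.37 on TPM. The members of these lists are short transcripts, with median lengths of 0.21, 0.24 and 0.45 relative to the other genes. Across genes, which are not independent replicates, log2 fold change increased with transcript length (Spearman's rho 0.21).

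**Figure D2:**
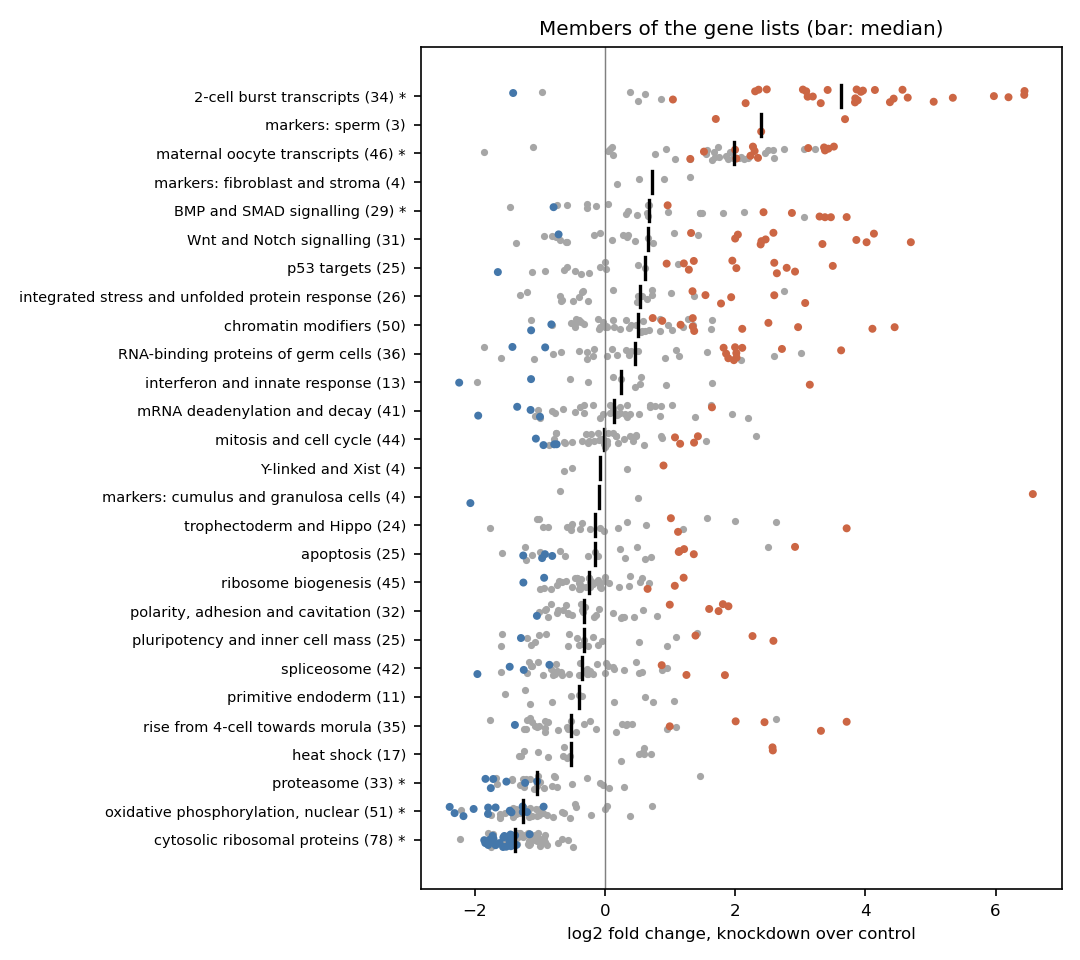
Log2 fold change, knockdown over control, of each measured member of the 27 tested lists, with the number of members in brackets, a bar at the median, coloured points for members past the edgeR threshold and an asterisk for lists past camera. The 2-cell list has the highest median (3.63) and the cytosolic ribosomal list the lowest (−1.39).

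Genes of BMP and SMAD signalling were higher as a list, with a median log2 fold change of 0.68, which was 1.14 with library sizes alone and 1.34 on TPM. Of 29 members 7 rose and 1 fell, in equal numbers adjusted over the list alone, and 10 rose and 2 fell without knockdown replicate 3. The rises included the BMP target genes Id2, from 2.92 to 38.2 CPM (log2 fold change 3.71 ± 0.38 SE, edgeR adjusted p = 0.00574), and Id1, from 1.82 to 20.1 CPM (3.47 ± 0.44, edgeR adjusted p = 0.00889). Id4 rose from 1.41 to 10.3 CPM (2.87 ± 0.37, edgeR adjusted p = 0.00918). Gdf9, given above among the oocyte transcripts, is a further rise of this list, and Id2 also belongs to the morula and trophectoderm lists. Lists that share genes are not separate evidence. Smad4, chosen after its values were seen, was the member that fell (−0.79 ± 0.23, edgeR adjusted p = 0.0418), a change that was 0 on TPM. The list passed camera (adjusted p = 0.0276; adjusted p = 0.677 with an estimated correlation), and 15 of 19 alternatives kept it past the threshold. Thus 6 of 27 lists passed camera with the preset correlation and 0 with an estimated one. At an unadjusted p the 2-cell list (0.0243) was under 0.05 with an estimated correlation. Fry, which asks only whether a list's members move, called 5 lists, those of 2-cell, BMP and SMAD, p53, stress response and sperm genes.

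Among the 12 largest rises, transcripts almost absent from the controls appeared in the knockdown. Frg2f2 and Frg2f3 had 0 reads over the controls and 376 and 293 over the knockdown. Against a floor of 3 reads per library they were at least 31.9-fold and at least 24.7-fold higher, and at least 5.27-fold and at least 7.09-fold without knockdown replicate 2. Frg2f4 had 3 and 673 reads (ratio 170, 95% counting interval 57.9 to 827), or 3 and 127 without that library (ratio 47.2, 15.8 to 232). These 3 gene copies shared reads with each other or with further genes, and stood highest in knockdown replicate 2, at 14.65, 10.28 and 24.1 CPM. The olfactory receptor gene Olfr788 had 1 and 481 reads (ratio 365, 65.1 to 14400). The protease gene Prss46 had 2 and 402 (ratio 152, 41.9 to 1260) and the defensin gene Defb23 had 1 and 183 (ratio 139, 24.6 to 5510). Ccdc116 (log2 fold change 6.73 ± 0.53 SE, edgeR adjusted p = 0.00365) and Pira1 (6.71 ± 0.56, edgeR adjusted p = 0.00384) rose with reads shared with other genes. So did Pramef6 (6.71 ± 0.50, edgeR adjusted p = 0.00365) and Gsdmc3 (6.07 ± 0.85, edgeR adjusted p = 0.0103; 5.08 without knockdown replicate 3). Frg2f1 (6.21 ± 0.94, edgeR adjusted p = 0.0108) and the homeobox gene Obox3 (6.20 ± 1.34, edgeR adjusted p = 0.0222) were highest in knockdown replicate 3. Without it they stood at 4.66 and 3.56. Obox3 shared reads with other genes. Without that library the ratios were 217 (38.6 to 8630) for Olfr788, 51.6 (13.9 to 432) for Prss46 and 66.1 (11.4 to 2660) for Defb23. All control reads of Olfr788, Defb23 and Prss46 lay in control replicates 3, 1 and 2. With the respective control left out they were at least 36.4-fold, at least 15.6-fold and at least 36.4-fold higher. Without control replicate 3 the ratio was 304 (54.3 to 12000) for Frg2f4, 90.7 (24.9 to 751) for Prss46 and 82.5 (14.6 to 3280) for Defb23. Pramef6 stood at 7.45 without control replicate 3 and Obox3 at 6.79 without control replicate 1.

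The 12 largest falls included the translational regulator Paip2, at 473.9, 452.8 and 402.7 CPM in the controls and 98.75, 100.5 and 41.29 CPM in the knockdown (log2 fold change −2.47 ± 0.37 SE, edgeR adjusted p = 0.0108). Respiratory chain genes were among them, with Ndufa12 at −2.39 ± 0.62 (edgeR adjusted p = 0.0338) and Uqcrb at −2.31 ± 0.70 (edgeR adjusted p = 0.0471). The mitochondrial ribosomal protein gene Mrpl32 stood at −2.21 ± 0.34 (edgeR adjusted p = 0.0108). The histone genes H1f2 (−2.29 ± 0.54, edgeR adjusted p = 0.0266; −3.04 without knockdown replicate 1) and H2ac20 (−2.22 ± 0.53, edgeR adjusted p = 0.027) fell too. Both shared reads with other genes. The remaining falls were those of the centromere protein gene Itgb3bp (−2.62 ± 0.65, edgeR adjusted p = 0.0302), Pigbos1 (−2.30, edgeR adjusted p = 0.0188) and Uxt (−2.25, edgeR adjusted p = 0.0122). In the same edgeR test the others were Wdr83 (−2.25, adjusted p = 0.0418), Bst2 (−2.24, adjusted p = 0.0346) and C1galt1c1 (−2.23, adjusted p = 0.0124).

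**Figure D3:**
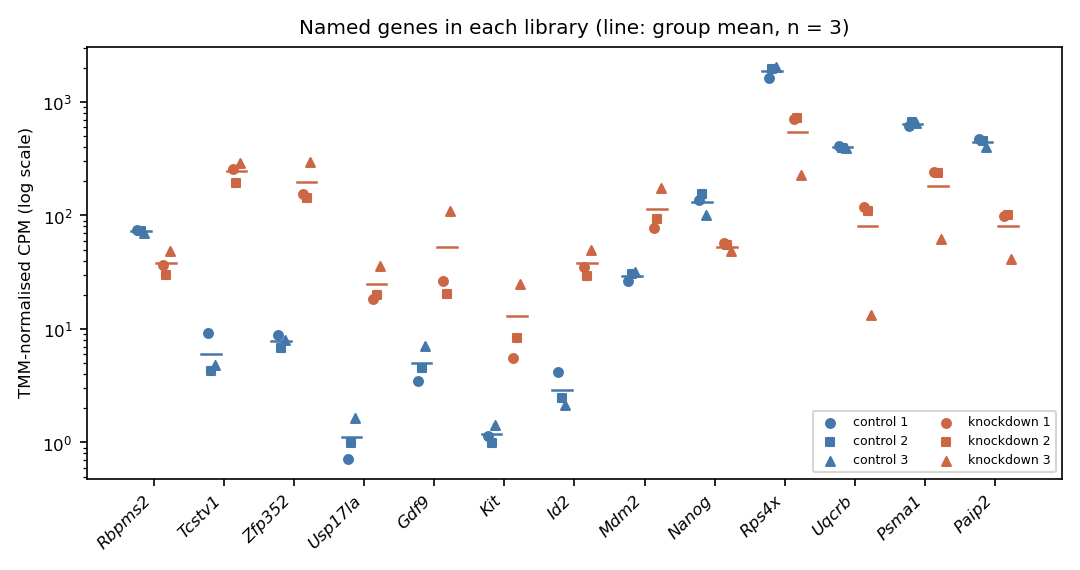
TMM-scaled CPM (log axis) of 13 named genes in each library, with a line at the mean of each group (n = 3), controls in blue and knockdown in orange. Tcstv1 stands near 6.07 CPM in the controls and 246 CPM in the knockdown, and Rps4x at 1869 and 548 CPM.

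Of the 6 factors of the first lineages, which separate towards the blastocyst, Nanog and Sox2 passed the test with all 6 samples, in opposite directions. Nanog, a factor of the inner cell mass, fell from 130 to 53.2 CPM (log2 fold change −1.29 ± 0.23 SE, edgeR adjusted p = 0.0157) with reads shared with other genes. Sox2 rose from 0.436 to 2.64 CPM (2.59 ± 0.50, edgeR adjusted p = 0.0178). Klf17 rose from 139 to 364 CPM (1.39 ± 0.28, edgeR adjusted p = 0.0195). Il6st rose by 2.27 ± 0.63 (edgeR adjusted p = 0.0387; 1.65 without knockdown replicate 3). Pou5f1 stood at 624 CPM in the controls and 209 CPM in the knockdown, a difference that did not pass the test (−1.58 ± 0.78, edgeR adjusted p = 0.151). The trophectoderm factor Cdx2 (−1.77 ± 0.60, edgeR adjusted p = 0.0627), its regulator Tead4 (−0.08 ± 0.35, edgeR adjusted p = 0.879) and the primitive endoderm factor Gata6 (−1.54 ± 0.61, edgeR adjusted p = 0.0908) did not pass either. The log2 fold changes of Pou5f1, Cdx2 and Gata6 were below 0 under all 19 alternatives. Without knockdown replicate 3 these 3 genes passed, with Pou5f1 at −1.05 (edgeR adjusted p = 0.00163), Cdx2 at −1.36 (edgeR adjusted p = 0.022) and Gata6 at −1.07 (edgeR adjusted p = 0.00109). Over the 19 alternatives their adjusted p ranged from 0.00163 to 0.28, 0.00643 to 0.201 and 0.000803 to 0.203. By list, 3 of 25 pluripotency genes rose and 1 fell, with equal numbers adjusted over the list alone (median −0.33, camera adjusted p = 0.313). Without knockdown replicate 3 the balance turned to 4 rises and 9 falls. Of 24 trophectoderm and Hippo genes 3 rose and 0 fell, again the same numbers adjusted over the list alone (median −0.15, camera adjusted p = 0.981), and without that library 6 rose and 1 fell (median 0.10). Among them were the Hippo pathway genes Mob1a (1.01 ± 0.22, edgeR adjusted p = 0.0224) and Sav1 (1.12 ± 0.29, edgeR adjusted p = 0.0323). Of 11 primitive endoderm genes 0 passed edgeR's test over all genes or adjusted over the list alone (median −0.40, camera adjusted p = 0.527; Gata4 1.07, Pdgfra −1.22, Dab2 −1.15). In that list 1 gene rose and 3 fell without knockdown replicate 3.

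Genes that rise from the 4-cell stage towards the morula gave 5 rises and 1 fall among 35 (3 and 1 adjusted over the list alone; median −0.52, camera adjusted p = 0.603). Without knockdown replicate 3 the balance turned to 6 rises and 9 falls. The lactate dehydrogenase gene Ldhb rose from 13.4 to 134 CPM (log2 fold change 3.32 ± 0.50 SE, edgeR adjusted p = 0.0108; 2.57 without knockdown replicate 3). The phosphate transporter gene Slc34a2 rose by 2.01 ± 0.43 (edgeR adjusted p = 0.0209; 1.35 without it), and Pramel6 fell (−1.38 ± 0.33, edgeR adjusted p = 0.0277). Of 32 genes of polarity, adhesion and cavitation 5 rose and 1 fell, in equal numbers adjusted over the list alone (median −0.33, camera adjusted p = 0.545), and without that library 5 rose and 5 fell. The rises included the adhesion molecule Epcam (1.90 ± 0.40, edgeR adjusted p = 0.0204) and the membrane linker Ezr (1.6 ± 0.35, edgeR adjusted p = 0.0227). They also included the polarity genes Pard3 (1.81 ± 0.45, edgeR adjusted p = 0.0307; 1.14 without knockdown replicate 3) and Mark2 (1.75 ± 0.50, edgeR adjusted p = 0.0411; 0.96 without it). Of 31 Wnt and Notch genes 12 rose and 1 fell, likewise adjusted over the list alone (median 0.66, camera adjusted p = 0.0682), and without that library 12 rose and 4 fell. They included the receptors Fzd7 (4.70 ± 0.73, edgeR adjusted p = 0.0113; 3.82 without knockdown replicate 3) and Fzd2 (4.02 ± 0.71, edgeR adjusted p = 0.0146; 3.05 without it). The ligand Jag1 (2.47 ± 0.55, edgeR adjusted p = 0.0234; 1.66 without it) and the scaffold gene Axin1 (1.32 ± 0.22, edgeR adjusted p = 0.0129) rose too.

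RNA-binding proteins of germ cells gave 10 rises and 2 falls among 36 (14 and 5 adjusted over the list alone; median 0.46, camera adjusted p = 0.174). Cpeb4 rose by 2.72 ± 0.36 on the log2 scale (SE, edgeR adjusted p = 0.0101) and the germline helicase gene Ddx4 by 1.86 ± 0.25 (edgeR adjusted p = 0.0101). Ybx2 rose by 2.0 ± 0.44 (edgeR adjusted p = 0.0233) and Igf2bp3 by 2.02 ± 0.43 (edgeR adjusted p = 0.0217; 1.35 without knockdown replicate 3). Of 50 chromatin modifiers 11 rose and 2 fell, in equal numbers adjusted over the list alone (median 0.51, camera adjusted p = 0.0872). The histone methyltransferase gene Suv39h1 stood at 2.11 ± 0.26 (edgeR adjusted p = 0.00815) and Kdm4d at 4.45 ± 0.63 (edgeR adjusted p = 0.0105; 3.68 without knockdown replicate 3). Setdb1 stood at 1.35 (edgeR adjusted p = 0.0165). Of 42 spliceosome genes 3 rose and 4 fell (2 and 3 adjusted over the list alone; median −0.36, camera adjusted p = 0.0682). Snrpa (1.84 ± 0.20, edgeR adjusted p = 0.00638) and Srsf11 (1.25, edgeR adjusted p = 0.012) rose while Snrpg (−1.96 ± 0.32, edgeR adjusted p = 0.0127) and Prpf6 (−0.85, edgeR adjusted p = 0.0273) fell. Of 45 ribosome biogenesis genes 3 rose and 2 fell (1 and 0 adjusted over the list alone; median −0.24, camera adjusted p = 0.136; Ddx10 1.21, Utp15 0.65, Rrp12 −0.94, Wdr12 −1.25). Of 41 mRNA decay genes 1 rose and 4 fell (0 and 0 adjusted over the list alone; median 0.14, camera adjusted p = 0.688; Cnot3 1.64, Lsm7 −1.35, Pan3 −1.14, Edc4 −1.0). Without knockdown replicate 3 the rises and falls were 11 and 6 for germ-cell RNA-binding proteins, 18 and 3 for chromatin modifiers, 7 and 16 for the spliceosome, 6 and 5 for ribosome biogenesis and 6 and 9 for mRNA decay.

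Targets of p53 gave 11 rises and 1 fall among 25, in equal numbers adjusted over the list alone (median 0.61, camera adjusted p = 0.0794; 0.0278 without knockdown replicate 3). Sesn2 rose by 2.60 ± 0.32 on the log2 scale (SE, edgeR adjusted p = 0.00815) and the repair gene Ercc5 by 2.64 ± 0.44 (edgeR adjusted p = 0.0127). Plk2 rose by 2.02 ± 0.34 (edgeR adjusted p = 0.0137), and Mdm2, the ubiquitin ligase that limits p53, from 29.6 to 115 CPM (1.96 ± 0.34, edgeR adjusted p = 0.0142, reads shared with other genes). Of 26 genes of the integrated stress and unfolded protein responses 6 rose and 0 fell (5 and 0 adjusted over the list alone; median 0.54, camera adjusted p = 0.174; 0.0333 without knockdown replicate 3). They included the chaperones of the endoplasmic reticulum Hspa5 (1.54 ± 0.23, edgeR adjusted p = 0.0108), Dnajb9 (1.78 ± 0.35, edgeR adjusted p = 0.0181) and Calr (1.34 ± 0.22, edgeR adjusted p = 0.0124). Of 17 heat shock genes Hspa1a (2.57 ± 0.41, edgeR adjusted p = 0.0118) and Hspa1b (2.58 ± 0.47, edgeR adjusted p = 0.0159), which share reads, were the 2 that rose, over all genes and adjusted over the list alone (median −0.53, camera adjusted p = 0.688). Of 25 apoptosis genes 5 rose and 4 fell, in equal numbers adjusted over the list alone (median −0.16, camera adjusted p = 0.603). They included the rises of Bbc3 (2.92 ± 0.54, edgeR adjusted p = 0.0162), Bcl2l11 (1.22, edgeR adjusted p = 0.0151) and Bid (1.14, edgeR adjusted p = 0.0243) and the fall of Endog (−1.26, edgeR adjusted p = 0.0189). Bbc3 is also counted in the p53 list, and Sesn2 in both the p53 and the stress response list. Of 13 interferon and innate response genes 1 rose and 2 fell, likewise adjusted over the list alone (median 0.25, camera adjusted p = 0.843). These were Irf1 (3.15, edgeR adjusted p = 0.0207; 2.54 without knockdown replicate 3), Irf9 (−1.14, edgeR adjusted p = 0.0426) and Bst2. Of 44 cell cycle genes 4 rose and 4 fell (0 and 0 adjusted over the list alone; median −0.01, camera adjusted p = 0.752). Cdc25c (1.15), Ccnd1 (1.37) and Pttg1 (1.43) rose and the mitotic kinase gene Cdk1 fell (−0.95, edgeR adjusted p = 0.0277). Without knockdown replicate 3 the rises and falls were 12 and 2 for p53 targets, 12 and 1 for the stress responses, 4 and 5 for heat shock, 7 and 11 for apoptosis and 6 and 7 for the cell cycle.

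Markers of other cells are given here as CPM of the library total without TMM factors. Summed cumulus and granulosa markers reached at most 9.36 CPM. Summed stromal markers lay between 4.47 and 7.32 CPM in the controls and at 10.5, 15.5 and 20 CPM in the knockdown. Summed sperm markers were 12.5, 12.2 and 13.7 CPM in the controls and 49.4, 29.7 and 120 CPM in the knockdown. Most of this was Odf2, at 94.2 CPM in knockdown replicate 3. All 3 tested sperm markers rose, adjusted over the list alone as well (camera adjusted p = 0.0732). They were Odf2 (log2 fold change 1.70, edgeR adjusted p = 0.036; 1.04 without knockdown replicate 3), Ldhc (3.69, edgeR adjusted p = 0.0296; 2.59 without it and 4.40 without control replicate 3) and Tssk6 (2.40, edgeR adjusted p = 0.0266). The protamine genes Prm1 and Prm2 were at 0 and 0.107 CPM in that library. Too few blood markers were tested for a list test. Their summed level was 16.5, 15.9 and 23.0 CPM in the controls and 23.5, 36.4 and 85.7 CPM in the knockdown, mostly Hba-a1 (edgeR adjusted p = 0.125). Of 4 tested cumulus markers Pgr fell (−2.07, edgeR adjusted p = 0.0154) and Ptgs2 rose from 0 to 40 reads, at least 3.31-fold. Both passed adjusted over the list alone (camera adjusted p = 0.843). Of 4 stromal markers 0 passed edgeR's test in either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 0.55), and 1 rose without knockdown replicate 3. Of 4 Y-linked genes Uty rose (0.89, edgeR adjusted p = 0.0327) and was the 1 gene past the test adjusted over the list alone (camera adjusted p = 0.981), while Xist was not listed in the tables.

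Values of the lists that did not pass camera depended on the scaling, because medians lay about 0.5 higher with library sizes alone. The medians of the morula, trophectoderm, pluripotency, primitive endoderm, polarity, ribosome biogenesis, spliceosome, apoptosis, heat shock, cell cycle, cumulus and Y-linked lists were above 0 with library sizes alone or on TPM. Among the other lists that did not pass, medians on TPM were 1.44 for p53 targets, 1.21 for the stress responses, 1.13 for germ-cell RNA-binding proteins, 1.05 for chromatin modifiers, 0.97 for Wnt and Notch and 0.83 for mRNA decay. The 6 lists past camera kept the sign of their median under every scaling tried. The mean had the opposite sign to the median and to camera's direction in the trophectoderm, heat shock, apoptosis, cell cycle, cumulus and Y-linked lists. In the mRNA decay and interferon lists camera's direction was down while median and mean were above 0. The number of called genes depended on single libraries, with 156 calls without control replicate 1, 19 without control replicate 2 and 889 without control replicate 3. It was 5691 without knockdown replicate 3, against 3438 in edgeR's test of all 6 samples. In each of these fits 0 of the 3438 calls changed sign. Leaving out a control also leaves the test fewer samples, so a lost call need not mean a smaller change. Reads were also shared with other genes in at least 1 library by Fbxw15, Psma3, Wdr83, Cnot3, Pan3, Wdr12, Snrpa, Hspa5, Bcl2l11, Endog, Ccnd1, Tssk6, Pgr, Uty and Hba-a1, so their single values are uncertain. Of 128 named genes, 113 kept their direction but lost their call without control replicate 2, 101 without control replicate 1 and 72 without control replicate 3.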

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

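Scaling by library sizes alone, limma-trend on log2(TPM + 1) and the test of genes with whole counts were chosen after the data were seen. The count of called genes, 3438 by edgeR's test, was 5444 with DESeq2, 6900 with sample quality weights, 1974 among genes with whole counts (1813 of them at least 2-fold, where fewer genes were tested) and 19 to 5691 with 1 sample left out (19 to 3282 at least 2-fold), where the fit pooled the spread. Without control replicate 2 it was 19, without control replicates 1 and 3 it was 156 and 889, and without knockdown replicate 3, which had the lowest quality weight (0.09), it was 5691. The other settings gave 3009 to 4242. On TPM 61 calls had the opposite sign, and 0 under every other setting. The number of lists past camera was 5 to 10 with 1 sample left out, 9 without a filter, and 0 with an estimated correlation, and fry's mixed test called 22. BMP and SMAD signalling was past the threshold in 15 of 19 settings and the other 5 lists in all 19, with medians of 2.01 to 4.08 for the 2-cell list and −1.67 to −0.73 for the ribosomal list. Rbpms2 stood at −0.44 with library sizes alone, −0.14 on TPM, and −1.12 to −0.80 with 1 sample left out, past the threshold there only without knockdown replicate 3. With the replicate number as a block, 3053 genes were called, 2607 of them shared, Rbpms2 was at −0.95 (adjusted p = 0.0502) and 9 lists passed. Same-numbered samples deviated together only in part (r = 0.155, 0.047 and 0.198 across genes). Each control correlated best with the knockdown sample of its own number, but knockdown replicate 2 correlated best with control replicate 1 (0.154). With so few samples these values cannot tell whether the numbers pair the samples. Tead4 changed sign with the stricter filter (0.01), quality weights (0.26), library sizes (0.37) and TPM (0.58), and ranged from −0.28 to 0.24 with 1 sample left out. Rbpms changed sign with library sizes (0.18) and TPM (0.36) and ranged from −0.60 to 0.04 with 1 sample left out, and Smad4 was 0 on TPM. For all of these the cause was not tested. Quantile normalization, median shifts, rescaling to TPM and other pseudocounts, planned for normalized values only, were not run because the tables held counts. Simulated genes changed 2-fold were recovered in 1.5% of cases with the fitted dispersion and in 70.1% with a lower one. Far fewer genes were changed there than were called here, so these shares need not hold for the real comparison.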

Other observations

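The gene families below and the genes named for their abundance or function were chosen after the results were seen. So were the tests of nearness to the 2-cell stage, of shared reads in each list alone, of the protamine genes and of single cell types. The other tests and their bounds were written before those tests were run. Those on raised or lowered lists and on knockdown replicate 3 nevertheless address patterns already seen in the results. Among 159 families of at least 10 tested genes with a shared symbol stem, the mitochondrial ribosomal proteins had the smallest p by camera (adjusted p = 5.07e-14; adjusted p = 0.828 with an estimated correlation, as for each family named below). Of 78 members 31 fell and 0 rose, with a median log2 fold change of −1.30. Genes with the symbol stem Eef, translation elongation factors among them, gave 5 falls and 0 rises among 12 (median −1.33, camera adjusted p = 0.00725). COMMD proteins gave 3 and 0 among 10 (median −1.37, adjusted p = 0.00743) and subunits of the RNA exosome 3 and 0 among 10 (median −1.20, adjusted p = 0.0381). On the other side, 15 of 22 olfactory receptor genes rose and 0 fell (median 3.30, camera adjusted p = 1.66e-07), with reads shared in 15 of the 22. Of 22 Fbxw genes, a family with many oocyte members, 15 rose and 2 fell (median 3.16, adjusted p = 0.000101), with reads shared in 14. The medians of these families kept their sign under every scaling tried, and on TPM those of the first 4 families were −0.62, −0.61, −0.77 and −0.41.

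The most abundant transcripts of the knockdown libraries included several that were far lower in the controls. Gm52800 stood at 2012, 1488 and 1687 CPM in the controls and 20160, 23280 and 51800 CPM in the knockdown (log2 fold change 4.20 ± 0.55 SE, edgeR adjusted p = 0.00943). Clec16a went from 448 to 10600 CPM (4.57 ± 0.69, edgeR adjusted p = 0.0108; 3.55 without knockdown replicate 3) and Ipp from 470 to 8597 CPM (4.19 ± 0.42, edgeR adjusted p = 0.00574). The counts of these 3 genes were not whole in any of the 6 libraries, so their reads were shared with other genes. Among genes without shared reads, chosen singly and covered by no list test, Gadd45b rose from 10.9 to 208 CPM (4.26 ± 0.44, edgeR adjusted p = 0.00574) and Gadd45g from 1.15 to 18.6 CPM (4.02 ± 0.42, edgeR adjusted p = 0.00574). The imprinted cell cycle inhibitor gene Cdkn1c rose from 5.96 to 52.1 CPM (3.12 ± 0.32, edgeR adjusted p = 0.00574). Within the 2-cell list, Zscan4c rose from 0.784 to 11.7 CPM (3.88 ± 0.54, edgeR adjusted p = 0.0103; 3.19 without knockdown replicate 2), with shared reads. Each of these genes, the 3 abundant ones included, was higher in 3 of 3 knockdown libraries than in any control. The groups were apart in most tested genes, so for genes chosen by their rise this is not separate evidence.

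Reads shared between gene copies do not account for the rise of oocyte transcripts, as the 37 members with whole counts in every library lay 2.05 above the median of all genes (bootstrap 95% interval 1.64 to 2.26; 2.05 also over both lists). For the 2-cell list shared reads stay open, since 8 members had whole counts and lay 2.01 above that median with an interval of −1.0 to 3.81. After the trend on transcript length was removed, the median of both lists was 2.48 (2.26 to 2.90), against 2.29 before. The correction did not lower this median, which argues against length bias as a cause of the joint rise in these libraries. These intervals resample genes, which are not independent replicates, so they describe these libraries and leave out the spread between libraries. That knockdown embryos were nearer the 2-cell stage stays open, as the list of transcripts that rise towards the morula, which would then be lower, gave a camera adjusted p of 0.60. A response to the knockdown was not tested apart from the time of collection.

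The fall of ribosomal, respiratory chain and proteasome transcripts was weakened by a correction for length, from a median of −1.31 to −0.64 over the 162 members (bootstrap 95% interval −0.74 to −0.57). Length bias therefore may carry part of the fall, and in these libraries a part remained after the correction. The intervals of the ribosomal list (−0.78 to −0.49) and the proteasome list (−0.90 to −0.49) taken singly reached above −0.5. Intervals in this paragraph resample genes, which move together, and leave out the spread between libraries. Removal of the trend on GC content left −1.35 (−1.43 to −1.30). A few abundant genes taking up the counts would lower other genes alike, whereas these members lay −1.35 (−1.41 to −1.23) from the median of all genes. That value restates the fall by which these lists were picked, so it is not a separate test of this explanation. For the part that length did not remove, a response to the knockdown and a difference in stage or time of collection stay open. They were not tested apart.

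Knockdown replicate 3 differed from the other knockdown libraries partly along the change that these showed against the controls (Pearson's r = 0.44 across genes, which are not independent replicates). The differences compared share knockdown replicates 1 and 2 with opposite signs, so chance would push this r below 0, and a larger response to the morpholino in that sample is a candidate explanation. Rbpms2 itself was least lowered in that sample, at 48.46 CPM against 36.94 and 30.05 CPM in knockdown replicates 1 and 2. In TPM it stood at 64 there, above every control, although a morpholino need not lower the mRNA of its target. The difference of knockdown replicate 3 also followed transcript length (Spearman's rho 0.30), on the bound set for that test, so a technical difference of that library stays open. The change of the other knockdown libraries against the controls increased with length too (Spearman's rho 0.16), so a shared length trend could add to the r of 0.44. The test of other cells, written before it was run, asked for all 4 marker sums to stay under 100 CPM. It was undecided because the sperm sum was 120 CPM. In the tests of single types, chosen after the results were seen, cumulus and granulosa markers (7.43 CPM) and stromal markers (20 CPM) stayed under that bound. So did blood markers (85.7 CPM), of which Hba-a1 was 82.6 and Hba-a2, Alas2, Lyz2 and Cd74 were 0.749, 0, 0.428 and 1.93. The stromal and blood sums were nevertheless higher than in any other library. The sperm sum passed the bound through Odf2 and Ldhc (94.2 and 24.4 CPM), but the protamine genes, abundant in sperm, summed to 0.107 CPM. Only these later tests argue against cells of the 4 types, and other cell types were not tested.

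Of the 10 ways to split the 6 libraries into 3 and 3, 1 gave as many called genes as the real grouping, which was the real one itself with 3438, and the highest other split gave 0. With 10 splits the share cannot fall under 0.05.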
